A study of Mus musculus with 16 samples.

How the data were processed

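Spleens of 4 TRaWT and 4 TRaGS mice were used. Per the labels' protocols, CD4+ T cells were enriched magnetically and sorted into CD25- and CD25+ fractions, RNA was purified on columns, and libraries were made with a 3' mRNA kit that reads in the forward orientation. The submitters' processing notes name the genome build GRCm38. The aligner, the counting program and the sequencer settings are not given in the sources used here. The authors deposited 2 tables of normalised counts, 1 per subset, with 47643 Ensembl gene identifiers and 8 libraries each. The deposited values are a signal unit, read counts divided by 1 factor per library, and each table was normalised by itself. In each library the values were whole multiples of 1 step, within a tolerance of 0.001 (100% of values in all 16 libraries), which gave the reads back. On those reads edgeR called 3 genes in CD4 and 90 in Treg. The deposited factors equalled median-of-ratios factors computed from those reads. All columns of both tables were used. No replicate pair agreed within sampling noise, and each library was counted as 1 sample from 1 animal. Depth is the total of recovered reads. The kit description names no molecular identifiers, so reads may include copies of 1 molecule, and genes that share 3' sequence with a near-identical copy, such as Rps13-ps2 and other pseudogenes, are uncertain.

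Symbols came from the reference gene table, which matched 47224 identifiers, and coordinates from GENCODE mouse release 21 on the same build. Genes with a mean of at least 5 normalised counts over the 8 libraries of a subset were tested on log2(value + 1) with limma 3.58.1 (R 4.3.3), with a variance trend and Benjamini-Hochberg adjustment at 0.05. Fold changes are TRaGS minus TRaWT on that scale, which understates changes of low genes. Values are given as mean ± SD of normalised counts with n = 4 and fold changes as log2 ± SE. In CD4 limma estimated infinite prior degrees of freedom, so each gene's variance was the trend value at its level. The SEs and p-values of CD4 genes thus do not measure the spread of the single gene between animals. In Treg the prior degrees of freedom were 36.8, so a gene's own spread counted in part. Tests were made within a table. The difference between subsets was tested with limma on each animal's Treg minus CD4 log2 difference, in which a constant between the tables cancels.

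The tests, the alternatives, the rule for named genes and 38 gene lists were fixed before the data were examined. Lists with at least 5 tested genes (32 in each subset) were tested with camera at a preset correlation of 0.01; 6 lists were too small. The rule named up to 12 genes per direction with the largest change among called genes without overlap between genotypes, passing over predicted genes, pseudogenes and receptor segments, or the 5 with the smallest p where fewer than 5 passed. It also named 11 fixed genes, up to 6 called members of each list or 2 members where none was called, and the 5 with the smallest p per direction for the difference between subsets. Some genes that the rule names are not reported here.

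Alternatives were pseudocounts of 0.5 and 5, no filter and a mean of at least 20, upper-quartile scaling, quantile normalisation, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, array weights, the replicate number as a block, leaving out each library (both libraries of an animal for the comparisons of subsets), the 2 TRaGS animals whose numbers lie near those of the TRaWT animals (replicates 1 and 2, called early) alone, and leaving out other-cell and sex-linked genes. Lists were also tested with an estimated correlation and with fry, and the difference between subsets in 1 model of all libraries (statmod 1.5.0). Thinning to equal depth, a correction for transcript length and GC content (values for 99.8% of tested genes) and a variance trend on mean expression were added after seeing the data. Figures were drawn with matplotlib 3.10.9.

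The fits were tested on simulated data: 5 sets of negative binomial counts with the means, dispersions and sizes of the real libraries and 200 changed genes each. Of genes changed 4-fold, 30.9% were recovered in CD4 and 58.4% in Treg, and of those changed 2-fold 2.09% and 28.1%. False calls were 4.27% and 6.10% of calls, and none of the changed genes was called in the wrong direction. The test of the difference between subsets, run on 9705 to 9740 genes, recovered 0% at either size, and with the variance trend on mean expression 19.9% of 4-fold and 2.09% of 2-fold changes. A list raised 2-fold was called in 5 of 5 sets in each subset, and over the 5 sets 0 other lists were called in CD4 and 2 in Treg. Simulated genes were drawn independently, so these counts do not measure list calls that arise from correlation between genes. In the real data, splits of the animals other than by genotype gave up to 6 lists in CD4 and 12 in Treg.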

Results

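The series profiled 2 subsets of splenic CD4+ T cells from TRαGS mice, whose thyroid hormone receptor alpha (gene Thra) has lost its ability to bind DNA, and from their wild-type littermates. The subsets were CD25- CD4+ T cells, labelled naive and called CD4 below, and CD25+ CD4+ regulatory T cells (Treg). The groups are named TRaGS and TRaWT as in the labels. Each of 8 mice, 4 per genotype, gave 1 library of each subset, which makes 16 libraries in 4 groups of 4. The libraries were 3' tag libraries, in which reads come from the 3' ends of polyadenylated transcripts. The values are normalised read counts, and whole reads were recovered from them. Recovered depth was 2679119 to 5095278 reads per CD4 library and 2912038 to 4154027 per Treg library. A single gene, Gm42418 (chromosome 17, 39846958 to 39848788, GRCm38), which overlaps ribosomal RNA sequence, took 21.1% to 41.1% of the reads in CD4 and 20.8% to 33.0% in Treg. CD4 libraries resembled each other less than Treg libraries did: the median Spearman correlation of a library with the other 7 of its subset was 0.762 to 0.835 in CD4 and 0.880 to 0.911 in Treg.

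Thra itself (ENSMUSG00000058756, chromosome 11, 98740638 to 98769006) was measured at 122 ± 51.2 normalised counts in TRaWT CD4 cells and 115 ± 48.7 in TRaGS CD4 cells (SD, n = 4 each). In Treg it stood at 133 ± 15.3 and 135 ± 52.9. The log2 fold changes were -0.07 ± 0.54 in CD4 and -0.05 ± 0.28 in Treg (SE), with limma adjusted p = 0.990 and 0.981, and their sign changed between alternative settings. A mutation that abolishes DNA binding need not alter this mRNA, so the level does not check the genotype labels. Thrb, encoding the related receptor, was low in both subsets, at 35.3 ± 54.7 against 7.39 ± 8.98 in CD4 and 4.78 ± 2.98 against 13.5 ± 12.2 in Treg.

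The series asks how signalling through this receptor affects Treg, and the genotypes were compared first in the CD25- CD4 cells. Myo6 (ENSMUSG00000033577, chromosome 9, 80165031 to 80311729), encoding an unconventional myosin motor, rose from 123 ± 58.0 to 1121 ± 245 normalised counts in TRaGS (log2 fold change 3.31 ± 0.34, adjusted p = 1.33e-18). Bcl2, encoding an anti-apoptotic protein, rose from 1212 ± 223 to 2481 ± 224 (1.05 ± 0.21, adjusted p = 0.00237). Klf3, a Krüppel-like transcription factor, rose from 2179 ± 234 to 3989 ± 592, Pdlim4 from 154 ± 54.1 to 496 ± 76.2 and Resf1 from 1213 ± 284 to 2394 ± 620, each with adjusted p = 0.00702. In these 5 genes every TRaGS value lay above every TRaWT value. Of all genes tested in CD4, 3.16% had no overlap, near the 2.86% given by chance for 4 against 4. Of 22 alternatives, Klf3 and Resf1 lost their call in 8 each, Pdlim4 in 6, Bcl2 in 2 and Myo6 in 0. Smc4, a condensin subunit named after its values were seen because its groups overlapped, was the remaining call (0.67 ± 0.15, adjusted p = 0.0275).

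These 6 genes, all higher in TRaGS, were the calls among 10426 genes tested with limma, while 539 had an unadjusted p under 0.05. No gene was called lower. The 5 lower genes with the smallest p and no overlap were Daam1 (-2.71 ± 0.78), Igfbp4 (-0.81 ± 0.24), Gpd2 (-1.73 ± 0.51), Hist2h2ac (-4.48 ± 1.33) and Anxa5 (-1.95 ± 0.61), with adjusted p from 0.510 to 0.611. The count was 1 without the filter on low values, 2 with upper-quartile scaling, 3 with edgeR and 10 with DESeq2 on the recovered reads, and 27 with TRaGS replicates 1 and 2 alone. It was 3 without TRaWT replicate 2, 3 or 4, and 4 of the 35 ways to split the 8 animals gave at least 6 genes.

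Of 32 gene lists tested in CD4, camera with a preset correlation called 4. Interferon-response genes fell as a group: 24 of 27 had negative fold changes, with a median of -0.75 (adjusted p = 8.86e-06, and adjusted p = 0.0433 with an estimated correlation). No member passed singly, over all genes or adjusted over the list alone, and Isg15, which encodes a ubiquitin-like modifier induced by interferon, had -2.56 and Xaf1 -1.35. Mitochondrially encoded mRNAs were called higher, 7 of 8 with positive values and mt-Nd4 at 0.53, none past the threshold over all genes and 4 higher adjusted over the list alone (adjusted p = 8.62e-07, and adjusted p = 0.498 with an estimated correlation). The naive and quiescence list was also called higher, with Klf3 its 1 member past the threshold over all genes and 3 higher and 1 lower when adjusted over the list alone (adjusted p = 0.00254, and adjusted p = 0.659 with an estimated correlation). Thyroid hormone-regulated genes were called lower, 9 of 10 negative, led by Gpd2, the mitochondrial glycerol-3-phosphate dehydrogenase, with none past the threshold over all genes and 1 adjusted over the list alone (adjusted p = 0.0203, and adjusted p = 0.498 with an estimated correlation). The other 28 lists had adjusted p from 0.0514 to 0.930. TRaGS replicate 2 held 3.71% mitochondrial mRNA, against 1.26% to 2.42% in the other 7 libraries, and without it only the interferon list of these 4 stayed called, with adjusted p = 0.118 for mitochondrial mRNAs (mt-Nd4 0.24), 0.290 for the naive list and 0.187 for thyroid hormone-regulated genes (Gpd2 -0.89). The latter were also lost without TRaWT replicate 2 (adjusted p = 0.158) or TRaGS replicate 3 (0.0634), the count of lists was 2 with DESeq2 and 1 with fry, and 11 of the 35 splits gave at least 4.

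In Treg the comparison bears on the series' question directly. Il1rl1 (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415), which encodes the IL-33 receptor ST2, rose from 115 ± 51.5 to 584 ± 148 normalised counts in TRaGS Treg (log2 fold change 2.44 ± 0.27, adjusted p = 9.14e-08). The calcium-binding protein genes S100a4 and S100a6 rose from 216 ± 37.2 to 717 ± 45.8 and from 280 ± 66.0 to 858 ± 229. Klrg1, a receptor found on differentiated effector cells, rose from 247 ± 71.3 to 685 ± 118, and the transcription factor genes Rora and Maf rose from 437 ± 95.4 to 1043 ± 105 and from 1012 ± 220 to 2032 ± 133. Bcl2 fell from 1837 ± 171 to 1050 ± 225 and Foxp1, a transcription factor of quiescent T cells, from 2512 ± 83.0 to 1484 ± 324. Foxp3, the lineage-defining factor of Treg, differed by less than the spread between animals, at 1165 ± 65.4 and 1156 ± 199.

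Limma called 106 of 11051 genes in Treg, 81 higher and 25 lower in TRaGS, and 95 of them had no overlap between the genotypes. Of all genes tested, 5.07% had no overlap, against 2.86% by chance for 4 against 4. Among called genes without overlap, the largest increases were in genes nearly silent in TRaWT: Ltb4r1, a leukotriene B4 receptor, went from 1.04 ± 0.97 to 60.8 ± 38.7, Atp6v0d2 from 3.72 ± 4.38 to 68.0 ± 14.5, Itga2 from 2.49 ± 2.27 to 41.1 ± 19.5 and Sostdc1 from 1.34 ± 0.69 to 31.2 ± 12.7, and the chemokine receptor gene Ccr3 had a log2 fold change of 4.12. Next by size among these, beside Il1rl1, were Nhsl2, Il18rap, Zcchc18, Ttc39c, Gna15 and Csf1, with log2 fold changes from 2.00 to 2.97. The largest decreases without overlap were in Gng12 (-2.96 ± 0.72), Ctsw (-1.39 ± 0.29), Prg4 (-1.29 ± 0.33), Igfbp4 (-1.22 ± 0.28) and Lta (-1.19 ± 0.29). Ifi213, Slfn5, Evl, Treml2, Pml, Smad7 and Slfn1 followed among genes without overlap, from -1.17 to -1.01. Smad7 encodes an inhibitor of TGF-beta signalling, and Igfbp4 lies on chromosome 11 (99041244 to 99054392) near Thra. Of 22 alternatives, Gna15 lost its call in 14, Nhsl2 in 12, Gng12, Prg4 and Lta in 8 each, Itga2 and Pml in 7 each, Smad7 in 6 and Ccr3 in 5, and Sostdc1 in 7 of 21, while the other genes named here by size lost theirs in 0 to 4. The count was 62 without the filter on low values, 42 with TRaGS replicates 1 and 2 alone, 56 without TRaGS replicate 3 and 61 without TRaGS replicate 4, and no other split of the animals gave more than 2.

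**Figure D1:**
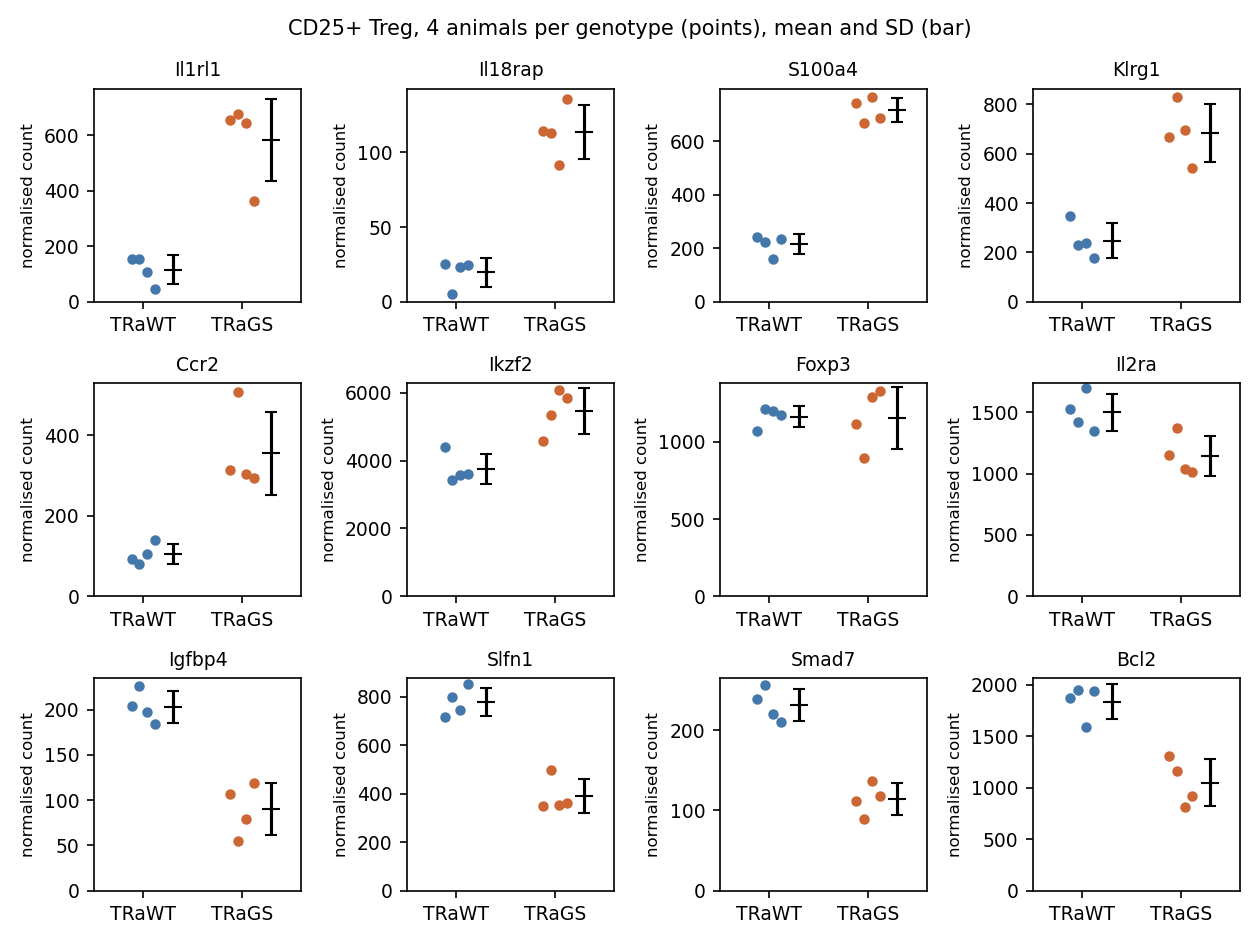
Normalised counts of 12 genes in Treg, with each point 1 animal (4 TRaWT, 4 TRaGS) and the bar the mean with SD on a linear axis from 0. Il1rl1, S100a4 and Klrg1 lie higher and Bcl2 and Smad7 lower in every TRaGS animal, while the Foxp3 means are 1165 and 1156.

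Effector Treg and memory genes rose together. Of 18 effector Treg genes 8 rose and none fell over all genes tested, and 13 rose adjusted over the list alone, with a median log2 fold change of 1.23 (camera adjusted p = 1.12e-24, and adjusted p = 0.00343 with an estimated correlation). They included Icos, a costimulatory receptor (794 ± 208 to 1410 ± 289), Prdm1, encoding Blimp-1 (57.7 ± 22.2 to 172 ± 40.3), and Tnfrsf1b, encoding TNF receptor 2 (299 ± 45.0 to 549 ± 58.6). Of 19 memory and activation genes 9 rose and none fell, 13 adjusted over the list alone, with a median of 0.65 (adjusted p = 9.23e-28, and adjusted p = 0.00343 with an estimated correlation). Among these were Ccr2, a chemokine receptor (104 ± 25.0 to 355 ± 102), and the integrin gene Itgb1 (593 ± 44.6 to 1284 ± 261). Cd44 had 218 ± 61.8 and 324 ± 56.7 and did not pass (adjusted p = 0.317).

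Lists of helper lineage genes were called higher too. In the Th2 list 3 of 5 genes rose, also 3 adjusted over the list alone: Il1rl1, Gata3 (891 ± 146 to 1418 ± 228) and the chemokine receptor gene Ccr4, the latter losing its call in 8 of 22 alternatives (adjusted p = 2.56e-07, and adjusted p = 0.0147 with an estimated correlation). In the Th1 list 3 of 11 rose, also 3 adjusted over the list alone: Il18rap (19.6 ± 9.77 to 114 ± 18.2), Il18r1 (253 ± 57.9 to 510 ± 70.7) and Cxcr3, of which the first 2 encode the IL-18 receptor subunits (adjusted p = 3.08e-06, and adjusted p = 0.0291 with an estimated correlation). In the Th17 list 2 of 6 rose, Rora and Ccr6, the latter losing its call in 15 of 22 alternatives, and 3 adjusted over the list alone (adjusted p = 2.61e-05, and adjusted p = 0.0291 with an estimated correlation). Of 22 alternatives, Cxcr3 lost its call in 5 and Gata3 in 4. Il1rl1, Gata3 and Cxcr3 also belong to the effector Treg list. In the trafficking list 5 of 17 rose, Itga4, Itgb1, Ccr4, Ccr6 and Cxcr3, with 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.00162, and adjusted p = 0.0655 with an estimated correlation). All of these but Itga4 also belong to the memory, Th2, Th17 or Th1 list. Icos belongs to both the effector Treg and the memory list, so the lists are not separate pieces of evidence. In the Tfh list 1 of 11 rose, Sostdc1, and 3 adjusted over the list alone (adjusted p = 0.0122, and adjusted p = 0.0850 with an estimated correlation), and the list was lost without TRaGS replicate 3 (adjusted p = 0.0586) or 4 (0.0679). The Treg core list was not called (adjusted p = 0.0605), with 3 of 23 genes higher over all genes and 7 higher and 4 lower adjusted over the list alone. In it Ikzf2, encoding Helios, rose from 3751 ± 432 to 5466 ± 668, Nrp1 from 840 ± 91.5 to 1472 ± 175 and Itgae from 68.2 ± 34.3 to 167 ± 28.1, with the calls of Ikzf2 and Itgae lost in 7 of 22 alternatives each. Il2ra, encoding CD25, had 1500 ± 151 in TRaWT and 1141 ± 165 in TRaGS (adjusted p = 0.271), and Ctla4 had 243 ± 72.3 and 266 ± 131.

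Genes of naive and quiescent T cells fell: 17 of 18 had negative fold changes and 3 passed, Foxp1, Igfbp4 and Satb1 (1692 ± 232 to 1125 ± 181, lost in 7 of 22 alternatives), or 7 adjusted over the list alone (adjusted p = 5.62e-12, and adjusted p = 0.0290 with an estimated correlation). Ccr7, a chemokine receptor gene, had 357 ± 34.5 and 243 ± 28.8 without passing (adjusted p = 0.281). Like Igfbp4, Ccr7 lies near Thra on chromosome 11 (99144196 to 99155077). Both also belong to the list of Thra neighbours, which was not called (camera adjusted p = 0.170). For these genes, naive list membership and position near Thra cannot be told apart. Ribosomal protein genes fell as a group, 58 of 72 negative with a median of -0.29, of which 5 passed, among them Rps14, Rps20, Rpl8 and Rps15, and 9 adjusted over the list alone (adjusted p = 1.08e-10, and adjusted p = 0.0290 with an estimated correlation). Of 22 alternatives, Rps15 lost its call in 18, Rpl8 in 11, Rps20 in 10 and Rps14 in 5. Interferon-response genes were called lower with the preset correlation, 21 of 26 negative with a median of -0.40, none past the threshold over all genes and 1 lower adjusted over the list alone (adjusted p = 0.00162, and adjusted p = 0.231 with an estimated correlation). Mitochondrially encoded mRNAs were also called lower, 7 of 7 negative and 0 past the threshold over all genes or adjusted over the list alone (adjusted p = 0.0176, and adjusted p = 0.416 with an estimated correlation). So were dissociation stress genes, 11 of 17 negative, with Jun past the threshold, though lost in 13 of 22 alternatives, and 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.0369, and adjusted p = 0.488 with an estimated correlation). Each of these 3 calls was lost without single libraries, the interferon list without TRaWT replicate 1 (adjusted p = 0.0799) or TRaGS replicate 1 (0.0594) and the mitochondrial list without TRaWT replicate 1 (0.0885), TRaWT replicate 3 (0.0758) or TRaGS replicate 3 (0.232). The dissociation list was lost without TRaWT replicate 3 (0.167) or 4 (0.560) and TRaGS replicate 1 (0.171) or 2 (0.126). The other 19 lists had adjusted p from 0.0605 to 0.924, and the count of lists was 7 with an estimated correlation. The median or mean differed in sign from the test in 6 CD4 lists (receptor partners, dissociation stress, ribosomal proteins, unfolded protein, glucocorticoid response and trafficking) and in the Treg list of T cell receptor response, none of them called.

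**Figure D2:**
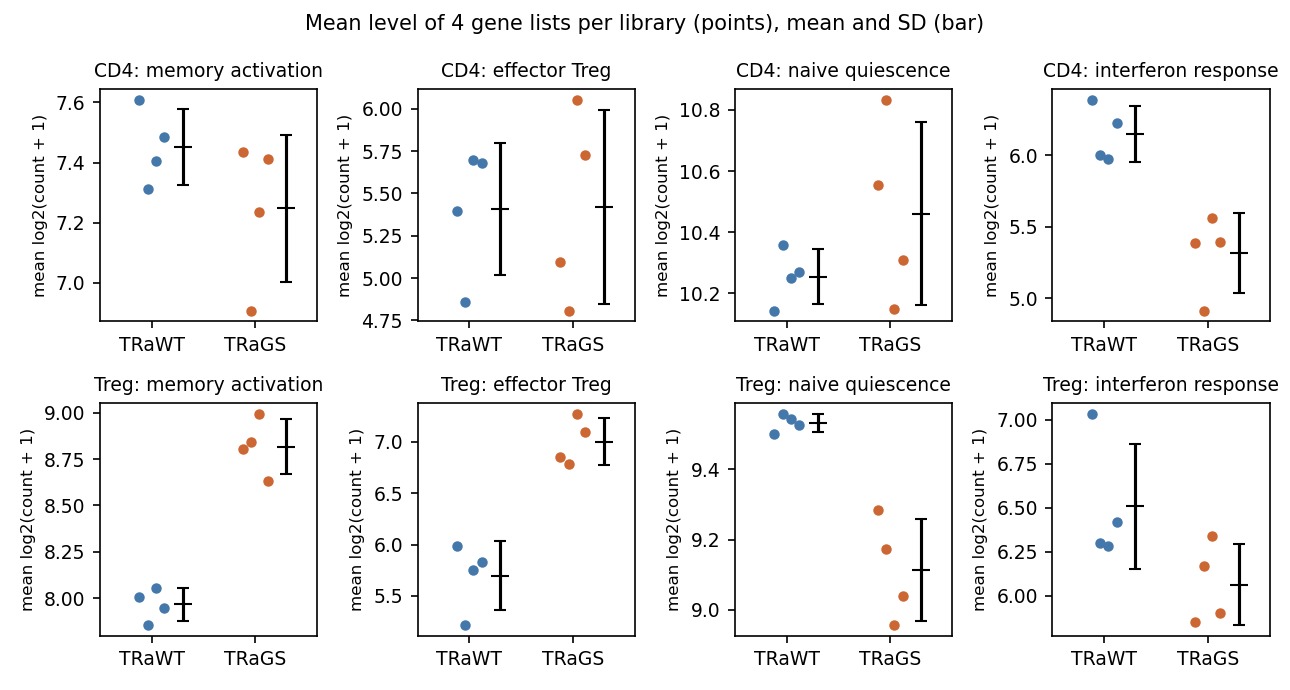
Mean log2(normalised count + 1) of 4 gene lists per library, for CD4 (top) and Treg (bottom), with points for animals and bars for mean and SD on axes that do not start at 0. In Treg all TRaGS libraries lie above TRaWT for the memory and effector lists and below for the naive list.

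Beside the effector and memory genes, the summed share of reads in markers of other cell types, CD8 T cells aside, was 0.0760% ± 0.0116 in TRaWT and 0.114% ± 0.0156 in TRaGS Treg (SD, n = 4 each, exact permutation test, two-sided p = 0.0286, the smallest that 4 against 4 allows). In CD4 it was 0.0923% ± 0.0189 and 0.0727% ± 0.0122 (exact permutation test, two-sided p = 0.171). The B cell list was called higher in Treg, 15 of 17 positive, with Ighm rising from 945 ± 134 to 1510 ± 268, the 1 member past the threshold over all genes or adjusted over the list alone (list adjusted p = 0.000944, and adjusted p = 0.382 with an estimated correlation). Without TRaGS replicate 1 the list was not called (adjusted p = 0.0761). Cd79a, below the filter, had 0.585 ± 0.676 in TRaWT and 0.486 ± 0.574 in TRaGS Treg. Igkc had 43.4 ± 23.5 and 143 ± 185, with 421 in TRaGS replicate 1 and 49.1 to 52.2 in the other TRaGS libraries. Cd74 had 176 ± 25.7 and 259 ± 36.6 without passing. Plasma cell markers, too few to test as a list, were positive in 4 of 4 and summed to 14.6 ± 11.8 and 109 ± 112, a rise of 94.5 that was 40.6 without TRaGS replicate 1. Other types gave 402 ± 35.6 and 399 ± 18.0 for CD8 T cells, 43.4 ± 21.3 and 31.6 ± 11.5 for NK cells and 882 ± 120 and 933 ± 109 for macrophages and dendritic cells, and the 1 neutrophil marker, Mmp9, had a log2 fold change of -2.02.

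Whether the genotype effect differed between the subsets was tested on each animal's Treg minus CD4 difference. Bcl2 was higher in TRaGS CD4 cells (1.05) and lower in TRaGS Treg (-0.83), a difference of -1.87 ± 0.32. Ccr2 went the other way, with -0.91 in CD4 and 1.75 in Treg, a difference of 2.66. Myo6 and Klf3 had 3.31 and 0.87 in CD4 against 0.59 and -0.15 in Treg. The limma test fixed for this comparison called 0 of 9914 genes, these 4 included, with a smallest adjusted p of 0.281 and 591 genes at an unadjusted p under 0.05. That test also recovered 0% of genes changed 4-fold in simulated data of this size, so its count of 0 does not show that the effects were alike. Its variance trend followed the mean Treg minus CD4 difference of a gene, not its expression. With the trend on mean expression, 19.9% of 4-fold changes were recovered in the same simulated sets, so sample size alone did not give the 0%. Other models called 15 genes (edgeR), 41 (DESeq2), 4 (all 16 libraries with the animal as a random effect) and 17 (variance trend on mean expression, chosen after seeing the data), and Bcl2, Ccr2, Klf3 and Myo6 were the 4 genes called by each of these.

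**Figure D3:**
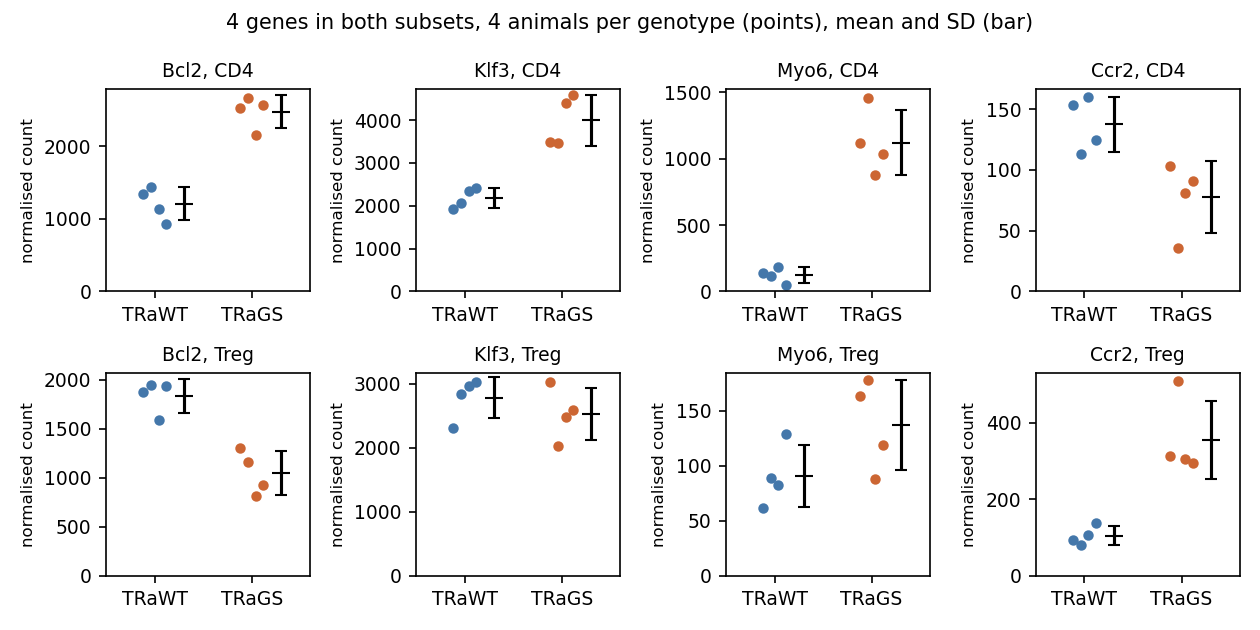
Normalised counts of Bcl2, Klf3, Myo6 and Ccr2 in CD4 (top) and Treg (bottom), each point 1 animal and each bar the mean with SD, on linear axes from 0. The tables of the subsets were normalised separately, so levels are compared between genotypes within a panel; Bcl2 is higher in TRaGS in CD4 (2481 against 1212) and lower in Treg (1050 against 1837).

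By the rule for named genes, the smallest p for a more positive effect in Treg belonged to Hist2h2ac, Plek, Aldh1b1, 4930589O11Rik and Lyn, and for a more negative one to Bcl2, Ptrh2, Rps13-ps2, Gss and 2310061I04Rik. Across the 9914 genes tested in both tables the fold changes of the subsets had a Pearson correlation of 0.027 and a Spearman correlation of 0.026, across genes, which are not independent replicates. Of the 35 splits of the animals 20 gave a Pearson correlation at least as large. Most of these genes were called in neither subset, so the correlation does not measure likeness among called genes. Of genes called in Treg, Sostdc1 (3.81 in CD4, 3.74 in Treg), Gna15 (2.37, 2.05) and S100a4 (1.37, 1.75) had similar values in both. Others, such as Cxcr3 (-1.22, 1.40) and Il18rap (-0.40, 2.68), had opposite signs. These examples were picked after their values were seen. Bcl2 was the 1 gene called in both subsets, higher in CD4 and lower in Treg, where independent lists give 0.0151 genes. For genes called higher in both, 0 were found and 0.0478 expected. The pair of directions was not chosen beforehand, so 0.0151 understates what is expected for any pair.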

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

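The tests of other-cell RNA, of Foxp3-expressing cells and of the early animals for the Treg pattern, and of other-cell RNA in the CD4 library, were chosen after the results were seen, as was the variance trend on mean expression. Samples were looked at for 1 value far from the other 3 of its group, as the gap to the nearest value divided by the range. This marked 14 of 198 groups, where chance gives about 9.9.

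In CD4, the gap was 0.951 for Gpd2 and 0.915 for Anxa5, both in TRaGS replicate 2, and 0.938 for Klf9 in TRaWT replicate 2. In TRaWT Treg it was 0.943 for Il18rap, 0.927 for Gata3 and 0.870 for Rora in replicate 2, 0.929 for Zcchc18 and 0.856 for Nrp1 in replicate 4, and 0.876 for Evl in replicate 3. In TRaGS Treg it was 0.917 for Il1rl1 in replicate 4, and 0.889 for Slfn1 and 0.878 for Ccr2 in replicate 2. TRaWT Treg replicate 1 stood apart in total reads (0.889) and in the share of mitochondrial ribosomal RNA (0.857). The genotype effect differed between the subsets for Bcl2 (Treg minus CD4 -1.87), Myo6 (-2.72), Klf3 (-1.01) and Ccr2 (2.66), each past the threshold in 4 alternative models but not in the limma test fixed beforehand.

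Effector and memory genes were higher in TRaGS Treg. Later animals alone are argued against, since the lower of the early TRaGS animals lay 0.82 log2 units above the highest TRaWT animal, where the TRaWT SD was 0.20. A smaller share of Foxp3-expressing cells stays open: the lower 95% limit of the Foxp3 log2 fold change was -0.32, which leaves room for a small loss. The 95% interval of Il2ra, not adjusted for the number of genes, was -0.68 to -0.12, wholly below 0. That of Ikzf2, also not adjusted, was 0.29 to 0.79, wholly above 0. The Treg core genes went both ways, with Il2ra at -0.40 (limma adjusted p = 0.271), Ikzf2 (0.54), Nrp1 (0.81) and Itgae (1.38) past the threshold upward, and 12 of 23 positive (mean 0.16, median 0.059). RNA from other cell types stays open as well: summed markers of other cells, plasma cells not included, rose by 944 normalised counts against 6870 for the called members of both lists, a ratio of 0.137, which was above the bound of 0.1 set for excluding it, though Ighm alone gave 565 of the rise and without it the ratio was 0.0552, or 0.030 without TRaGS replicate 1 also. Of the rise of 944, the B cell list gave 919 and macrophage and dendritic cell markers 50.7 (ratio 0.0074). The NK cell, CD8 T cell and neutrophil markers fell, so the rise in this sum rests on B cell markers. Cell types without a list in the sum were not tested, so the ratio says nothing about them. A shift of TRaGS Treg toward an effector state is a hypothesis beside these. Of the other-cell lists tested, that of B cells, which the sort should remove, was called higher by camera. The call was lost with an estimated correlation (adjusted p = 0.382) or without TRaGS replicate 1 (adjusted p = 0.0761). Ighm, its 1 called member, did not follow its other members among the TRaGS libraries. Replicate 1 had the lowest Ighm of these (1150) and the highest sum of the other B cell markers (1454). The rise of Ighm therefore does not by itself show B cells.

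CD4 library TRaGS replicate 2 had the lowest median correlation with the others (0.762). RNA from other cells stays open: Hbb-bs had 177 normalised counts there (at most 25.0 in the others), Hba-a1 95.4, Lyz2 76.4 and Cd79a 49.5, but 13.3% of 45 tested markers lay above the other 7 libraries by more than their range, against 11.5% of all 10426 genes tested (Fisher exact test against the other genes, two-sided p = 0.641). With reads thinned to 1 depth, 10670 genes were detected in it, fewer than in each of the others, so fewer distinct molecules in the library may account for its place. No biological explanation was tested.

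Interferon-response genes were lower in TRaGS, with the call in Treg lost with an estimated correlation and without TRaWT replicate 1 (adjusted p = 0.0799) or TRaGS replicate 1 (0.0594). Both early TRaGS animals lay below the 4 TRaWT animals in both subsets, 4 of 4 values from 2 animals, which argues against later animals alone. In Treg the genotypes overlapped: the later TRaGS replicate 3 (mean log2 level 6.34) lay above TRaWT replicates 2 (6.30) and 3 (6.28). The authors' scaling is argued against by other scalings, under which the median nearest to 0 was -0.36 and both calls stayed. A lower interferon response in TRaGS cells is a hypothesis, and other differences between the animals were not tested.

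Other splits of the 8 animals into 4 and 4 were counted, 35 in all. For the 106 genes changed in Treg only the real split, 1 of 35, gave as many, and the highest other gave 2. For the 13 lists called in Treg it was also 1 of 35, but another split gave 12, so the number of lists is a weak measure. For the 6 genes changed in CD4 chance cannot be excluded: 4 of 35 splits gave as many, 1 of them 22 genes, which points to a structure among the CD4 libraries. The split with 22 genes set replicates 1 and 2 against 3 and 4, in both genotypes. In CD4 these are libraries numbered 1, 4, 7 and 16 against 19, 22, 31 and 34. They parted without overlap in depth (3387413 to 5095278 against 2679119 to 3188205 reads) and Gm42418 share (21.1% to 31.4% against 33.0% to 41.1%). They also parted in genes detected at thinned depth (10670 to 11456 against 11761 to 12032). Whether library order or depth gave the 22 genes was not tested. That split is 1 of 6 that part the early from the later TRaGS animals, and the other 5 gave 0 to 2 genes. Chance cannot be excluded either for the 4 CD4 lists (11 of 35 splits, highest other 6) or for the correlation of effects (20 of 35 splits, highest other 0.0782). For the difference between subsets the real count of 0 is reached by 35 of 35 splits (highest other 1), which tests nothing. With the variance trend on mean expression, the 17 genes of the real split were reached by 1 of 35, and the highest other gave 2.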

How the results depend on the processing

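The 3 added settings named in the methods were chosen after seeing the data. Over 214 named genes, lists and differences, 4673 comparisons with an alternative gave 4288 with the same direction and side of the threshold, 321 weaker, 28 stronger and 36 reversed. Where a value moved, the cause was not tested.

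CD4 genes changed (6) gave 1 with no filter, 2 with upper-quartile scaling, 3 with edgeR, 10 with DESeq2 (8 higher, 2 lower) and 27 with the 2 early TRaGS animals; quantile normalisation gave 5 higher and 1 lower. Upper-quartile scaling moved the median of all CD4 genes to -0.13. Treg genes changed (106) gave 62 with no filter and 42 with the early animals. CD4 lists (4) gave 2 with DESeq2 and 1 with an estimated correlation or fry; Treg lists (13) gave 7 with an estimated correlation. Genes differing between subsets (0) gave 15 with edgeR, 41 with DESeq2, 4 with the animal as a random effect and 17 with the variance trend on mean expression. The correlation of effects (0.027) gave 0.046 at a mean of at least 20, 0.042 with quantile normalisation, 0.052 with array weights and 0.0077 with the early animals.

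Leaving out 1 animal, with both of its libraries, gave 0 to 1 differing genes (1 without TRaWT replicate 4) and a correlation of 0.0098 to 0.049. Leaving out 1 library gave 3 to 9 CD4 genes, 56 to 108 Treg genes, 2 to 6 CD4 lists and 10 to 15 Treg lists. Thra ranged from -0.33 to 0.17 in CD4 and -0.29 to 0.13 in Treg, Foxp3 from -0.10 to 0.093 and Ctla4 from -0.23 to 0.26 in Treg. In CD4, Cd44 ranged from -0.30 to 0.17, Thrb from -2.28 to 0.019, Tbl1xr1 from -0.71 to 0.14, Tnf from -1.74 to 0.041, Txndc5 from -0.53 to 1.32 and Mmp9 from -0.74 to 0.40.

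Signs reversed, in genes not called, as follows. Treg Thra was 0.021 with edgeR, 0.015 with DESeq2 and 0.021 with array weights; CD4 Thra was 0.27 with the early animals and 0.15 with the length and GC correction. Treg Foxp3 was 0.015 with upper-quartile scaling and 0.037 with array weights, Treg Ctla4 -0.44 with the early animals and -0.055 with the length and GC correction, and Treg Hbb-bs 0.82 with the early animals. CD4 Txndc5 was -0.025 with a pseudocount of 0.5, -0.47 with array weights and -0.042 with thinning. CD4 Mmp9 was 0.01 with a pseudocount of 5, 0.12 with quantile normalisation, 0.44 with edgeR, 0.46 with DESeq2, 0.97 with the early animals and 0.012 with the length and GC correction. CD4 Klrb1f was 0.56 with edgeR and 0.59 with DESeq2; array weights gave -0.017 for Ccr7 and -0.14 for Hba-a1; Maf was -0.093 with the early animals.

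The replicate numbers do not pair the genotypes: same-numbered libraries are different animals, and their deviations correlated from -0.02 to 0.05. With the replicate block, 4 CD4 and 112 Treg genes were called. Thinning to equal depth (largest adjusted p of the Treg memory and effector lists 1.18e-24) and the length and GC correction (1.01e-24) argue against sequencing depth and transcript length or GC content as the cause of that pattern. Of 2-fold changes in simulated data, 2.09% were recovered in CD4, 28.1% in Treg and 0% in the test of the difference between subsets.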

Other observations

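Ikzf2, encoding Helios, had 422 ± 23.0 normalised counts in TRaWT CD4 cells and 655 ± 102 in TRaGS CD4 cells (SD, n = 4 each). It did not pass the test there (limma adjusted p = 0.947), beside its rise in Treg. In CD4 that test took the variance from the trend, not from the spread of Ikzf2 between animals. Cd4 mRNA had 907 ± 69.0 and 1097 ± 41.2 in CD4 and 736 ± 17.4 and 911 ± 90.0 in Treg. Klf9, a thyroid hormone-induced gene in other tissues, had 52.7 ± 9.24 in TRaWT Treg and 32.9 ± 5.33 in TRaGS Treg (adjusted p = 0.743). Igfbp4 fell in Treg and had a negative value in CD4 (-0.81, not past the threshold). These genes were singled out after their values were seen, apart from Ikzf2 and Klf9.

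Il1rl1, Il18r1 and Il18rap, which rose in TRaGS Treg, are neighbours on chromosome 1 (40429570 to 40551705, GRCm38). S100a4 and S100a6 are neighbours on chromosome 3 (90603771 to 90624181), and S100a11 lies on the same chromosome at 93520488 to 93526287. Mki67, a marker of cycling cells, rose from 102 ± 66.2 to 218 ± 77.3 in TRaGS Treg (adjusted p = 0.0496), with overlap between the genotypes and the call lost in 13 of 22 alternatives (adjusted p from 0.00380 to 0.352), while the proliferation list was not called (adjusted p = 0.263). Xist was measured in all libraries, with group means from 1120 to 2705, and the Y-linked genes Ddx3y, Eif2s3y and Uty had 0 reads in all 16, while Kdm5d had a read in 1 CD4 and 1 Treg library.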
